A study of Rattus norvegicus with 6 samples.

How the data were processed

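RNA sequencing libraries from bone of 6 rats (Rattus norvegicus) were compared, 3 from animals labelled as exercised and 3 from untreated controls. The labels give the tissue as bone, the cell type as osteocyte (the cell embedded in mineralized bone matrix) and the molecule as total RNA, and the series title describes moderate-intensity treadmill running in adult animals. Per the labels' protocols, RNA was extracted with a column kit and made into Illumina libraries. Duration, speed, bone site, sex and strand setting are not given in the sources used here. The series design text also mentions real-time PCR in further animals, which was not analysed here.

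The deposited table holds 1 whole number per Ensembl gene and library. Per the submitters' processing notes, CASAVA 1.8, fastp 0.19.5, HISAT2 2.1.0, StringTie and edgeR were used; the role and order of these tools are not given. The same notes name the builds hg38 and mm10, which are human and mouse assemblies, whereas every one of the 32883 gene identifiers in the table carries the rat Ensembl prefix. The rat build and annotation release are not given in the sources used here, so no coordinates are reported.

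Per the file headers the deposited columns are FPKM (fragments scaled by gene length and library size), but the values are whole-number counts by their properties, and they were treated as counts. All values were whole, and the column totals differed between libraries, from 14056743 to 18126584. An FPKM column with such a total implies a mean target length of 1e9 divided by the total, which came to 71.1 nt in the library with the smallest total and 55.2 nt in the one with the largest. The columns were assigned to samples through the library names in the labels, and 0 columns were left without a sample. The table has no rows that name no gene.

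The identifiers were looked up in the NCBI RefSeq gene table for rat assembly GRCr8, which holds 47357 genes. Its Ensembl column was empty, and 0 of the 32883 identifiers matched a symbol. The 37 lists of cell type and pathway genes and the 16 key bone genes fixed before the data were examined could therefore not be tested, and no marker of marrow, muscle, cartilage or fat could be read out. Of the individual genes, the text gives 4 by identifier. The rule fixed beforehand named genes past the threshold and, in a direction with fewer than 3 such genes, those with the smallest unadjusted p-values whose 3 exercised libraries all lay on one side of the 3 controls. It also asked for a gene symbol, a condition that had to be dropped, and its 8 genes per direction were cut to 2 per direction because the identifiers carry no names.

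The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, on genes kept by filterByExpr with its default minimum count of 10 and minimum total of 15, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The test used all 6 libraries and no covariate. This left 14495 genes; 12156 genes had a count of 0 in every library. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values (counts relative to library size) were scaled by the TMM factors, and principal components were computed on log2 CPM with a prior count of 2. Alternatives were DESeq2 1.42.0, limma 3.58.1 with voom or on log2(value + 1), other scalings, no filter, a replicate block, leaving out each library in turn, and a covariate. The limma fit on log2(value + 1) used the counts as deposited, without scaling between libraries.

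The edgeR and DESeq2 functions were tested on simulated negative binomial counts for the 14495 genes of the exercised against control comparison, with 200 genes changed. At a dispersion of 0.02, edgeR recovered 91% of the 2-fold and 98% of the 4-fold changes. With the dispersion estimated for each gene from these libraries, edgeR recovered 0% of the 2-fold and 0% of the 4-fold changes. In the same simulation DESeq2 recovered 5% and 53%, and 59 of its 117 calls were genes that had not been changed. The size of change that could be called was also measured on the real counts, by binomial thinning of 50 randomly chosen genes per fold in 1 group, in 20 draws, among genes with a mean of at least 1 CPM. Intervals on these recoveries are exact 95% Clopper-Pearson intervals and cover counting error only.

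The labels number the replicates 1 to 3 in both groups without saying that a number marks anything shared. The design text speaks of 3 rats per group, and p-values measure the spread between these 6 libraries. No 2 libraries of a group differed by as little as sampling noise: the chi-square statistic per degree of freedom was at least 70.1 in every pair of 1 group.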

Results

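The expression of 32883 annotated rat genes was measured by RNA sequencing in bone from 3 exercised rats and 3 controls, to find genes whose expression differed after treadmill running. The libraries were of similar depth. Control replicates 1, 2 and 3 held 15494159, 14056743 and 18126584 counts, and exercised replicates 1, 2 and 3 held 15660240, 14276864 and 15088881. Between 16910 genes (control replicate 3) and 18229 genes (control replicate 2) had at least 1 count. The share of counts taken by the 10 most abundant genes ranged from 16.6% in exercised replicate 3 to 27.5% in control replicate 3. The 100 most abundant genes took 34.6% and 52.5% of the counts in these libraries.

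The bone libraries differed as much within a group as between groups. The first principal component held 65.3% of the variance of log2 CPM, and the second held 16.4%. Control replicates 1, 2 and 3 scored -41.5, 52.7 and -126.1 on the first component, and exercised replicates 1, 2 and 3 scored -3.46, 1.52 and 116.8. The mean score was -38.3 ± 89.5 in controls and 38.3 ± 68.0 in exercised rats (SD, n = 3 each). The scores of the groups overlapped, and the difference of 76.6 did not pass a two-sided exact permutation test (p = 0.4; the smallest p that 3 against 3 allows is 0.1). Pearson correlations of log2 CPM across genes, which are not independent replicates, ranged from 0.80 to 0.96 between libraries of the same group and from 0.69 to 0.95 between libraries of different groups, with means of 0.883 and 0.879.

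**Figure D1:**
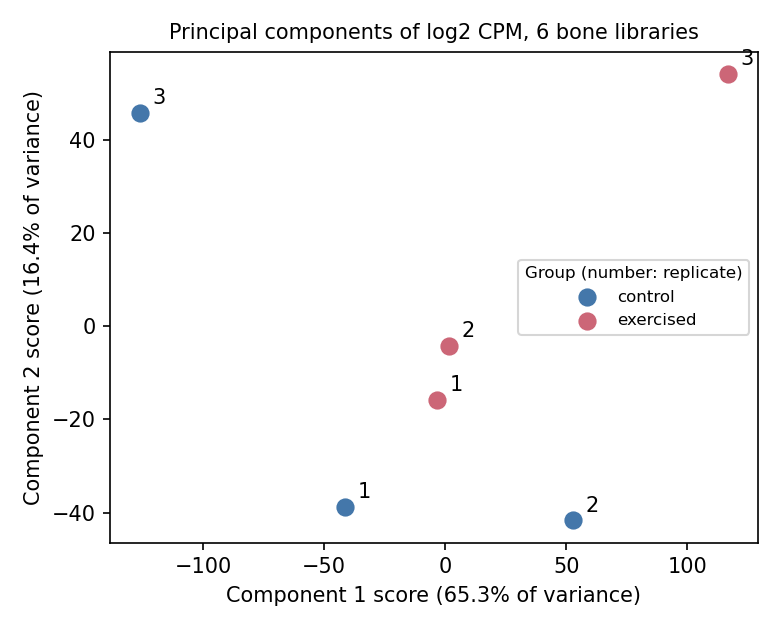
Scores of the 6 bone libraries on the first (x axis) and second (y axis) principal component of log2 CPM over the 14495 tested genes; each point is 1 library, coloured by group and numbered by replicate. Exercised replicates 1 and 2 lie between the controls on the first component, and control replicate 3 (-126.1) and exercised replicate 3 (116.8) lie at its ends.

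Large differences between single animals were frequent. Control replicates 2 and 3 differed by more than 4-fold in 2299 genes and by more than 10-fold in 1036 genes. Exercised replicates 1 and 3 differed by more than 4-fold in 1555 genes, whereas exercised replicates 1 and 2 did so in 204. Pairs of libraries from different groups differed by more than 4-fold in 268 genes (control replicate 1 and exercised replicate 1) to 3308 genes (control replicate 3 and exercised replicate 3), and the latter pair by more than 10-fold in 1345 genes. Between the group means of log2 CPM, in which the spread of 3 libraries is averaged, 463 genes differed by more than 4-fold and 7 by more than 10-fold.

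In the comparison of exercised with control bone, no gene passed the threshold. Of 14495 genes tested, 0 had an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.89. At an unadjusted p under 0.05 there were 247 genes, 103 higher and 144 lower in exercised bone, where 725 would be expected by chance on average. The other splits of the 6 libraries into 3 and 3 gave 37 to 2468 such genes, so 247 lies within their range. The number of unadjusted calls depended on single libraries: it was 54 without control replicate 1, 1315 without control replicate 2, 393 without exercised replicate 1 and 116 without exercised replicate 3. DESeq2's Wald test, run on 20681 genes without the filter on low counts, called 1 gene at an adjusted p under 0.05, and 552 genes at an unadjusted p under 0.05, where 1034 would be expected by chance. In 1069 genes (7.37%) the 3 exercised libraries all lay above or all below the 3 controls, a share that random assignment of 3 against 3 puts at 10%.

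The gene that DESeq2 called was ENSRNOG00000061169. Its counts were 4, 5 and 0 in control replicates 1, 2 and 3, and 63, 37 and 51 in exercised replicates 1, 2 and 3. With a bound of 3 counts, which covers counting error only, the 0 in control replicate 3 allows up to 0.208 CPM. Expression was 0.189 ± 0.164 CPM in controls and 3.26 ± 0.90 CPM in exercised bone (SD, n = 3 each). The log2 fold difference was 4.03 (SE 0.88, adjusted p = 0.89) by edgeR and 4.07 (SE 0.79, adjusted p = 0.0057) by DESeq2. However, DESeq2 called at least 1 gene in every other split of the 6 libraries into 3 and 3. The second gene with higher values in exercised bone was ENSRNOG00000047384, at 0.591 ± 0.153 CPM in controls and 2.67 ± 0.91 CPM in exercised bone. Its log2 fold difference was 2.16 (SE 0.48, adjusted p = 0.89 by edgeR and 0.67 by DESeq2).

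The smallest p-values among genes with lower values in exercised bone were those of ENSRNOG00000049020 and ENSRNOG00000013408. ENSRNOG00000049020 had 2.11 ± 0.37 CPM in controls and 0.566 ± 0.097 CPM in exercised bone (SD, n = 3 each). Its log2 fold difference was -1.89 (SE 0.43, adjusted p = 0.89 by edgeR and 0.964 by DESeq2). ENSRNOG00000013408 had 9.67 ± 4.09 CPM in controls and 1.5 ± 0.81 CPM in exercised bone, a log2 fold difference of -2.69 (SE 0.61, adjusted p = 0.89 by edgeR and 0.118 by DESeq2). The counts of ENSRNOG00000013408 were 205, 156 and 84 in controls and 28, 29 and 10 in exercised bone. In all 4 genes the libraries of the 2 groups did not overlap, which is how they were chosen, and 3 of the 4 rest on fewer than 100 counts per library.

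**Figure D2:**
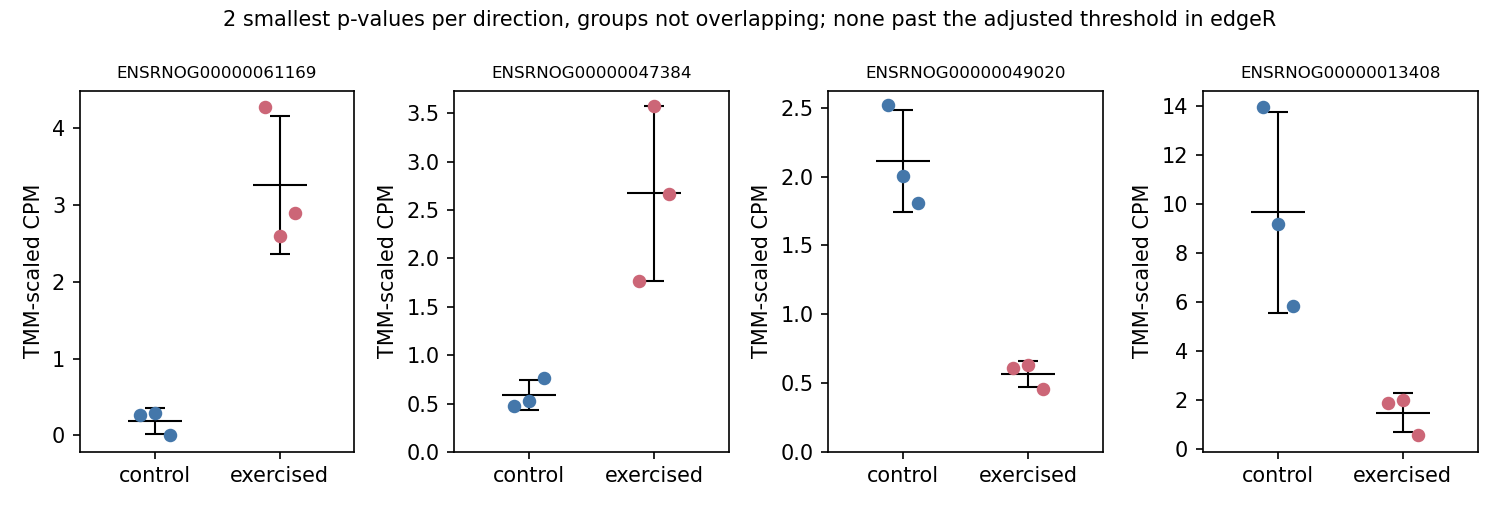
TMM-scaled CPM (y axes, each from 0 or just below) of 4 genes, the 2 per direction with the smallest p-values among genes whose groups do not overlap; points are single libraries, and the black bar and whiskers are the mean and SD of the 3 libraries of a group. ENSRNOG00000061169 lay at 0.189 ± 0.164 CPM in controls and 3.26 ± 0.90 CPM in exercised bone, and none of the 4 passed the adjusted threshold in edgeR.

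The spread between these libraries limited the size of change that could be called. When known changes were imposed on the real counts by thinning, edgeR called 0 of 1000 genes changed 2-fold (exact 95% interval 0 to 0.368%). It called 11.4% of genes changed 4-fold (9.50 to 13.5%), 33.8% of those changed 8-fold (30.9 to 36.8%) and 51.1% of those changed 16-fold (48.0 to 54.2%). DESeq2 called 13.8%, 61.2%, 80.8% and 90% of the same genes. In the separate simulation with the dispersion estimated for each gene, however, 59 of DESeq2's 117 calls were genes that had not been changed. Such calls were not counted on the thinned real counts. The settings differ, since edgeR recovered 0% of 4-fold changes in that simulation, so this share may not carry over. With 50 genes changed per fold in each draw, differences of 2-fold were not detected with edgeR in the fit reported here, which has no covariate. The adjustment depends on how many genes change, and settings with many more changed genes were not tried. The median standard error of a log2 fold difference was 0.42 over the tested genes.

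**Figure D3:**
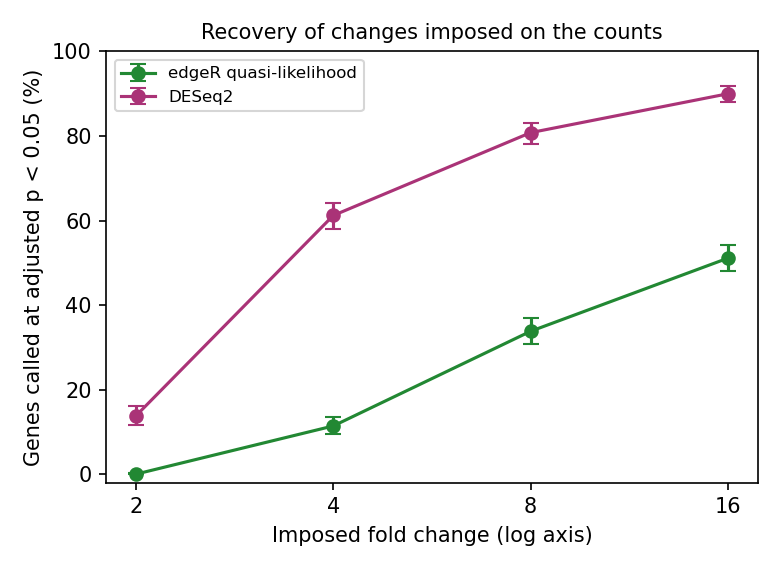
Share of genes called at an adjusted p under 0.05 (y axis, percent) against the fold change imposed by thinning the real counts (x axis, log scale), for edgeR and DESeq2; whiskers are exact 95% intervals over 1000 genes per fold. At 4-fold, edgeR called 11.4% and DESeq2 61.2%. Calls of genes that were not changed were not counted.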

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

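Of 18 alternatives for the number of genes changed between exercised and control bone, 16 gave 0 genes. Among these, the added fold threshold only restricts the 0 genes of the main fit, so it could give nothing else and is no support. DESeq2 gave 1, ENSRNOG00000061169, and replacing the adjusted by the unadjusted p gave 247. The alternatives with 0 genes were leaving out each library in turn, the replicate block, no filter, median-of-ratios factors, library size alone, the added fold threshold, and 5 chosen after seeing the data: limma on log2(value + 1), limma voom, scaling without the 100 most abundant genes, the first component as a covariate, and leaving out control replicate 3 and exercised replicate 3 together. With the replicate block there were 212 genes at an unadjusted p under 0.05. The replicate numbers did not pair the libraries: the deviations from the group means correlated at 0.31, -0.41 and -0.49 for numbers 1, 2 and 3, and not every library correlated best with its own number. The count at an unadjusted p under 0.05 ranged from 54 to 1315 when 1 library was left out. The 4 named genes kept their direction in all 16 alternative fits run for each. They were chosen because their groups do not overlap, so a reversal was hardly possible and the kept direction is no support. The log2 fold differences ran from 3.48 to 4.49 for ENSRNOG00000061169 and 1.85 to 2.39 for ENSRNOG00000047384. They ran from -2.01 to -1.74 for ENSRNOG00000049020 and -3.0 to -2.29 for ENSRNOG00000013408. Over these fits the adjusted p of ENSRNOG00000061169 ranged from 0.0057 (DESeq2) to 1.00. The share of variance on the first component was 77.3% over the 1000 most variable genes, against 65.3% over all tested genes, and moved by less than 10 percentage points in the other alternatives. Rescaling without the erythroid and muscle lists, and the list tests, were not run because no identifier matched a symbol; a second pseudocount, quantile normalization and limma with robust or untrended variance, planned only for a table of normalized values, were not run.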

Other observations

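Except for the thinning to 1 depth and the first-component covariate, whose expected outcomes were written down before their results were seen, the tests in this part were chosen after the result was seen. For the thinning, the outcome written down took a share that stayed close to its value as speaking against depth. A rule not written down then treats a share that hardly moves as no test, so that reading was set aside.

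The main structure of these libraries was a spread along the first component that ran through both groups. Of the variance of its scores, a share of 0.258 lay between exercised and control, where the 10 splits of the libraries into 3 and 3 give 0.2 on average, so whether exercise contributes stays open. Thinning all libraries to 14056743 counts moved the share of variance on this component only from 65.315% to 65.328%, and leaving out the 100 most abundant genes together with scaling by library size in place of TMM moved it to 64.856%; on values already scaled between libraries neither is a test of depth or of abundant genes. The median of each library was then removed, which takes out any factor common to its genes. Among the 9224 genes with a mean of at least 10 CPM, 26.2% still differed by more than 4-fold between highest and lowest library. A common shift alone therefore does not give these differences. Scaled values had already shown many of them, so this decides nothing further about abundant genes. The share of counts taken by the 10 most abundant genes was highest in control replicate 3 (27.5%) and lowest in exercised replicate 3 (16.6%). These libraries are the ends of the component, so whether abundant genes go with it stays open. The totals differ by only 1.29-fold, and depth alone does not order the scores. Exercised replicates 1 and 3 held 15660240 and 15088881 counts but scored -3.46 and 116.8. Control replicate 3, however, had both the largest total and the lowest score, so a part of the spread that goes with depth stays open. Whether the share of marrow, muscle or other tissue in the samples differed was not tested, since no marker could be matched.

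Whether this spread hid a difference between exercised and control was tested by adding the first component as a covariate to the edgeR fit. There were still 0 genes past the threshold. At an unadjusted p under 0.05 the real grouping gave 848 genes, and the highest of the 9 other splits gave 1426. In a check added afterwards, the covariate fit called 36.2% of 4-fold and 60.7% of 8-fold changes imposed on the real counts, but 2.3% of 2-fold changes. The result therefore argues only against many large changes that do not run along this component. The component is computed from the same values, so changes aligned with it would be removed by the covariate and were not tested. Small changes stay open.

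All 10 splits of the 6 libraries into 3 and 3 gave 0 genes by edgeR, the highest other split included. At an unadjusted p under 0.05, 6 of the 10 splits gave at least the 247 genes of the real grouping, and the highest other gave 2468, with control replicates 1 and 3 and exercised replicate 1 against the rest. That split parts the libraries by their score on the first component, which is computed from the same values, so it restates that spread. These 10 splits are too few for a share under 0.05. DESeq2, which called 1 gene between exercised and control, called up to 421 genes in the other splits and at least 1 in each.

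The column headers name FPKM, and rounded FPKM would be a different unit. A column of FPKM with these totals would need a mean target length of at most 71.1 nt (71.14 nt in control replicate 2), which argues against that reading. Counts that were scaled before deposit were not separately tested.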
